A study of Homo sapiens with 12 samples.

How the data were processed

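RNA was measured in 12 libraries from cultured human lung fibroblasts, in 4 groups of 3 libraries: DMSO, transforming growth factor β (TGFβ), pracinostat, and TGFβ plus pracinostat. Per the labels' protocols, poly-A RNA was selected from 200 ng of total RNA with an RNA quality number of at least 6, libraries were made with the TruSeq RNA Sample Prep Kit v2 and 12 cycles of PCR, and paired reads of 100 bases were read on a HiSeq 4000. This kit does not record the strand of a read, so reads from ACTA2 and from the antisense gene that overlaps it cannot be assigned to one or the other with certainty.

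Per the labels' protocols, the authors ran the MAPRSeq 3.0.0 pipeline, in which STAR with default settings aligned reads to the human genome build hg38 (GRCh38) and featureCounts of the Subread package counted reads over Ensembl 78 genes. The deposited table held the authors' RPKM values, that is read counts scaled to exon length and to the number of mapped reads of the library, with 1 column per library, as the column headers and the labels state. No further scaling between libraries was stated, raw counts were not used here, and the handling of reads that match several genes was not stated. Values of near-identical genes, such as the metallothioneins MT1X and MT1E, the actins ACTA2 and ACTG2, histone genes, and mitochondrial transcripts with nuclear copies, are therefore less certain than those of other genes.

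The table held 64253 gene identifiers, of which 56105 were in the reference annotation (release 44, GRCh38) used for positions and gene types, and 21751 were at 0 in every library. The 563 identifiers of Y-linked genes, XIST and TSIX were left out of every step. Each of the 12 value columns belonged to 1 sample, and none of the 66 pairs of libraries held identical values.

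The number of reads behind each column was recovered from genes with a single exon, in which an RPKM is a whole number of reads times a constant. With 1 base added to the annotated length, between 96.0% and 97.3% of low values (20 reads or fewer) were whole numbers of reads within a tolerance of 0.01, against between 26.8% and 63.5% without the added base. The recovered totals ran from 35.36 M to 58.16 M reads per library, and whether the authors counted reads or read pairs is not stated. Per the labels' protocols, sequencing yielded between 43 M and 65 M reads per sample. In recovered reads of single-exon genes, the difference between libraries of one group exceeded counting error, with a chi-square per degree of freedom between 2.64 and 17.1.

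Genes with an RPKM of at least 0.5 in at least 3 of the 12 libraries were tested, which left 19395 genes: 13036 protein-coding, 3127 long noncoding, 799 absent from the reference annotation, and the remainder of other types. Of these, 369 shared a symbol with another tested gene. Values were transformed as log2(RPKM + 0.5), a scale that understates fold changes of genes near or below an RPKM of 0.5. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a mean-variance trend) in 1 model with the 4 group means, two-sided, with Benjamini-Hochberg adjustment over the 19395 genes and a threshold of 0.05. Because all 12 libraries share 1 estimate of the spread per gene, errors given as SE are the model's. The 6 comparisons were TGFβ against DMSO, pracinostat against DMSO, TGFβ plus pracinostat against TGFβ, against pracinostat and against DMSO, and the interaction, which is the effect of pracinostat with TGFβ minus its effect without TGFβ. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

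In addition, 26 gene lists were fixed from background knowledge. They covered TGFβ/SMAD targets, matrix collagens and glycoproteins, collagen processing, contractile cytoskeleton, matrix-degrading proteases, fibroblast quiescence, inflammatory cytokines, interferon-stimulated genes, cell cycle, CDK inhibitors, genes often raised by HDAC inhibitors, histone deacetylases, acetyltransferases and acetyl readers, heterochromatin, neuronal genes, BMP signalling, serine, glycine and proline synthesis, glycolysis, cholesterol synthesis, pro-death genes, mitochondrially encoded transcripts, and markers of epithelial, endothelial, leukocyte, pericyte and mesothelial cells. Each list with enough measured members was compared with all other genes by camera (limma) with a preset correlation between genes of 0.01, adjusted over 144 tests. Camera was repeated with the correlation estimated from the data.

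Named genes followed a fixed rule. In every comparison 7 genes were read: ACTA2, COL1A1, FN1, CTGF, POSTN, PPARGC1A and CDKN1A. Another gene fixed in advance and 1 list member chosen by the rule are not reported here, but stayed in the tests, list results and gene totals. To these were added the 5 largest rises and 5 largest falls per comparison among genes past the threshold with a mean RPKM of at least 2 and the same direction in all 3 replicates, up to 4 members of each list described (or 2 if none passed), and, for each of 2 overlaps, the 10 genes with the largest product of changes. Clone-named genes, pseudogenes and small RNAs were passed over. The lists, tests, threshold, rule and alternatives were chosen before the data were examined; which lists have their members named in each comparison was chosen after the list results were seen.

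Sample titles carry a number shared by 1 library of each group, written here as replicate 1, 2 and 3, which the labels do not define as donors. The pairing was checked on values centred within each group: correlations across genes between libraries with the same number were between 0.23 and 0.37 for replicate 1, between 0.23 and 0.4 for replicate 2, and between 0.5 and 0.66 for replicate 3, and 3, 4 and 4 of the 4 libraries of each number correlated best with a library of their own number. Genes are not independent replicates. The number was used as a block in an alternative fit.

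Other alternatives were pseudocounts of 0.1 and 1, no filter, a filter at an RPKM of 1, median-of-ratios scaling, quantile normalization, only the groups compared, no mean-variance trend, a fold limit of 2 (log2 of 1), and leaving out each library or all 4 libraries of one replicate. Chosen after seeing the data were protein-coding genes only, the estimated correlation in the fit with the block, and the block without each replicate, as were the interaction regroupings that exchange groups only within a replicate (99 random ones and the real one). Overlaps of calls between comparisons were set beside the number expected for independent calls and beside 100 simulations of unchanged groups.

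The procedure was tested on simulated data with 19395 genes, 100 of them changed per fold size. The share of genes changed by a log2 of 1 that was recovered was 67% for TGFβ, 73% for pracinostat, 85% for both treatments against TGFβ, 65% against pracinostat, 73% against DMSO, and 44% for the interaction. At a log2 of 2 the shares were 94%, 96%, 95%, 95%, 95% and 80%, and between 0 and 2 unchanged genes were called. With the block the shares at a log2 of 1 were 89%, 92%, 90%, 82%, 90% and 75%, and between 9 and 16 unchanged genes were called. Among 24 simulated lists, camera called the 1 shifted list and no other. This was run for TGFβ against DMSO only. Apart from replicate differences the simulated genes varied independently, so other correlation within a list was not tested.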

Results

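Gene expression was measured in cultured human lung fibroblasts isolated from tissue of idiopathic pulmonary fibrosis, a scarring lung disease in which fibroblasts deposit collagen-rich matrix. The series examined genes regulated by TGFβ, a cytokine that turns fibroblasts into contractile, matrix-producing myofibroblasts, and by histone deacetylases (HDACs), enzymes that remove acetyl groups from histones and other proteins. Cells in medium with 0.1% serum received the solvent DMSO, TGFβ at 2 ng/mL, the HDAC inhibitor pracinostat (SB939) at 1 µM, or both agents, with 3 libraries per group. The labels used here did not give the treatment time.

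Reads recovered per library averaged 41.15 M ± 8.62 (SD, n = 3) for DMSO, 46.79 M ± 10.7 for TGFβ, 46.74 M ± 7.22 for pracinostat and 48.79 M ± 4.93 for both agents. The number of genes with an RPKM of at least 0.5 was 17578 ± 464 (SD, n = 3) in DMSO, 16056 ± 195 in TGFβ, 18297 ± 278 in pracinostat and 17569 ± 375 in both. Within groups, replicates 1 and 2 resembled each other most, with a correlation across genes between 0.987 and 0.992, whereas replicate 3 correlated with either at 0.964 to 0.975.

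Few markers of other lung cell types passed the filter. None of the 10 leukocyte markers and 1 of the 6 mesothelial markers (CALB2) passed the filter, so neither list was tested. Of 12 epithelial markers 4 passed (KRT18, KRT19, CLDN4 and MUC1), of 9 endothelial markers 3 passed (KDR, TEK and CLDN5), and of 8 pericyte markers 6 passed. In camera (limma), 0 of the 18 tests of these lists over the 6 comparisons passed, and 0 had an unadjusted p under 0.05. Single markers moved with the treatments: KRT19, a keratin of simple epithelia, was at 1.82 RPKM ± 0.176 (SD, n = 3) in DMSO, 0.353 ± 0.0747 in TGFβ, 5.17 ± 0.427 in pracinostat and 2.53 ± 0.18 in both. CALB2, a calcium-binding protein of mesothelial cells and neurons, was at 1.56 ± 0.272, 5.16 ± 1.01, 4.09 ± 1.28 and 6.22 ± 0.561 in the same order.

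The median of all 19395 tested genes moved by a log2 of -0.28 with TGFβ, 0.07 with pracinostat, 0.19 on adding pracinostat to TGFβ, -0.16 on adding TGFβ to pracinostat, -0.09 with both against DMSO, and 0.12 in the interaction. Median-of-ratios scaling moved these medians by 0.28, -0.07, -0.21, 0.16, 0.08 and -0.13, and quantile normalization by 0.26, -0.06, -0.2, 0.13, 0.07 and -0.13. Some list medians are therefore also given relative to the median of all genes. All 285 named results past the threshold had the same direction in 3 of 3 replicates, which the naming rule itself required of the largest rises and falls. Errors below are SE of log2 fold changes unless SD is given.

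With TGFβ alone, several genes of the myofibroblast response rose. ACTA2, smooth muscle actin (ENSG00000107796, GRCh38 chromosome 10, 88935074 to 88991339), went from 88.5 RPKM ± 34.5 (SD, n = 3) to 587 ± 188. This was a log2 change of 2.76 ± 0.34 (adjusted p = 1.02e-04). CTGF, a matricellular growth factor (ENSG00000118523, chromosome 6, 131948176 to 131951372), rose by 2.23 ± 0.23. FN1, fibronectin (ENSG00000115414, chromosome 2, 215360440 to 215436073), rose by 1.07 ± 0.15. COL1A1, the main chain of type I collagen (ENSG00000108821, chromosome 17, 50184101 to 50201632), rose by 0.78 ± 0.16. The 5 largest rises were the cytokine IL11 (6.02 ± 0.46, from 4.27 to 307 RPKM), the tendon transcription factor SCX (4.89 ± 0.44), MEOX1, a homeobox factor (4.57 ± 0.37), MDFI, an inhibitor of myogenic factors (4.33 ± 0.27), and elastin, ELN (4.06 ± 0.31). The 5 largest falls were the tight-junction gene CLDN11 (-4.80 ± 0.25), ADH1B, an alcohol dehydrogenase (-4.53 ± 0.17, from 13.2 to 0.079 RPKM), SLC7A14 (-3.75 ± 0.15), the retinol dehydrogenase RDH10 (-3.64 ± 0.15) and DTX4, an E3 ubiquitin ligase gene (-3.64 ± 0.35).

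Of 14 measured TGFβ/SMAD target genes, 12 rose and 1 fell, the same numbers when adjusted over the list alone (12 and 0 with either scaling), with a median change of 1.89, which is 2.16 above that of all genes (adjusted p = 1.73e-14). This call held with an estimated correlation (adjusted p = 0.0148) but not with that and the replicate as a block (adjusted p = 0.14, the highest over all alternatives). Members that rose included IL11, PMEPA1, a feedback inhibitor of SMAD signalling (3.58 ± 0.15), and BHLHE40 (3.12 ± 0.44). Of 29 matrix collagens and glycoproteins 14 rose and 3 fell, also when adjusted over the list alone, led by ELN, the cartilage matrix protein COMP (3.71 ± 0.41), the basement-membrane collagen COL4A1 (1.96 ± 0.36) and THBS2 (1.57 ± 0.27). The test of this list gave adjusted p = 7.25e-10 and adjusted p = 0.298 with an estimated correlation. Of 20 contractile genes 14 rose and 0 fell, likewise adjusted over the list alone, among them calponin CNN1 (2.28 ± 0.27), tropomyosin TPM1 (2.26 ± 0.26) and ACTG2 (1.96 ± 0.45). Their list test gave adjusted p = 2.71e-12 and adjusted p = 0.298 with an estimated correlation. Of 23 collagen processing and crosslinking enzymes 9 rose and 2 fell, likewise adjusted over the list alone, including the lysyl hydroxylase PLOD2 (1.94 ± 0.17) and lysyl oxidase LOX (0.90 ± 0.22). As a list they gave adjusted p = 6.15e-06 and adjusted p = 0.245 with an estimated correlation. With median-of-ratios scaling 18, 19 and 15 members of these 3 lists rose and 1, 0 and 1 fell, and with quantile normalization 15 matrix genes rose and 1 fell.

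The lists of 2 metabolic pathways also passed with TGFβ. Of 10 genes on the list of serine, glycine and proline synthesis 5 rose and 1 fell, also when adjusted over the list alone (5 and 2 with the replicate as a block). Those that rose included the proline enzyme ALDH18A1 (1.24 ± 0.13) and the mitochondrial folate enzyme MTHFD2 (0.94 ± 0.17), while SHMT1 fell by 1.02 ± 0.11. The list test gave adjusted p = 0.00556 and adjusted p = 0.629 with an estimated correlation, and quantile normalization ended the call (adjusted p = 0.0727, range over all alternatives 0.00275 to 0.629). Of 12 glycolysis genes 4 rose and 1 fell, also when adjusted over the list alone (8 and 0 with median-of-ratios scaling, 6 and 1 with quantile normalization, 5 and 2 with the block), including PFKP (0.83 ± 0.12) and the glucose transporter SLC2A1 (0.68 ± 0.16). For the list as a whole, the test gave adjusted p = 0.00731, adjusted p = 0.685 with an estimated correlation, and adjusted p = 0.0883 after quantile normalization (range over all alternatives 0.00463 to 0.685).

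Of 21 measured genes linked to a resting fibroblast state, 15 fell and 1 rose with TGFβ (16 and 1 adjusted over the list alone), with a median of -1.52, which is -1.24 relative to all genes (adjusted p = 0.00619, and 0.909 with an estimated correlation). Among them were BMP4 (-3.38 ± 0.19), the mesenchymal transcription factor TCF21 (-3.23 ± 0.28), the hepatocyte growth factor HGF (-2.98 ± 0.75) and CEBPD (-2.63 ± 0.22). Of 17 interferon-stimulated genes 12 fell, also when adjusted over the list alone, including IFIT3 (-2.48 ± 0.15) and IFIT2 (-2.14 ± 0.19). With median-of-ratios scaling 6 fell and 1 rose, and with quantile normalization 9 and 0. The list gave adjusted p = 0.0372, and 0.429 with an estimated correlation. Of 38 cell cycle genes 27 fell and 0 rose (28 and 0 adjusted over the list alone), including TYMS (-1.34 ± 0.19), AURKA (-1.18 ± 0.18) and TOP2A (-1.18 ± 0.22). With median-of-ratios scaling 9 fell, and 8 fell and 1 rose with quantile normalization. The cell cycle list gave adjusted p = 0.0307, 0.919 with an estimated correlation, and 0.0511 with the replicate as a block (range over all alternatives 5.36e-05 to 0.919). Of 13 mitochondrially encoded transcripts 12 fell, also with quantile normalization or adjusted over the list alone, including MT-CO1 (-0.69 ± 0.18) and MT-CYB (-0.65 ± 0.12). With median-of-ratios scaling 0 passed, which ended the list call (adjusted p = 0.183, against 0.043 without it and 0.919 with an estimated correlation, range over all alternatives 1.45e-04 to 0.919). MT-CO1 did not pass with no filter either (adjusted p = 0.156, range over all alternatives 4.03e-04 to 0.178). Of 10 measured HDAC genes 6 fell and 0 rose (8 and 0 adjusted over the list alone), led by HDAC11 (-1.01 ± 0.08) and HDAC10 (-1.0 ± 0.14), but with median-of-ratios scaling 2 fell and 1 rose, and with quantile normalization 3 and 1. The list test did not pass (adjusted p = 0.16, range over all alternatives 0.00224 to 0.693).

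The protease and inflammatory lists, with members in both directions, did not pass with TGFβ. Of 17 matrix-degrading proteases 1 rose and 6 fell, also when adjusted over the list alone (4 and 9 with the block): the aggrecanase ADAMTS4 rose by 1.09 ± 0.12, and ADAMTS1 (-3.24 ± 0.56), ADAMTS5 (-2.35 ± 0.47) and the plasminogen activator PLAT (-1.39 ± 0.15) were among those that fell. The median of this list was -0.5 and its mean -0.45, but the test pointed up (adjusted p = 0.882). Of 17 inflammatory genes 3 rose and 7 fell (3 and 8 adjusted over the list alone): LIF (3.53 ± 0.28) and TNFAIP6 (3.40 ± 0.20) rose, and PTX3 (-3.27 ± 0.42) and the chemokine CCL2 (-1.94 ± 0.25) fell. Its median was -0.58 and its mean -0.21, with a test that pointed up (adjusted p = 0.783).

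In total, 1769 genes rose and 7362 fell with TGFβ in limma, of which 515 and 1483 changed at least 2-fold. After median-of-ratios scaling 4103 rose and 3424 fell, and after quantile normalization 3378 rose and 3584 fell. PPARGC1A, a coactivator of mitochondrial biogenesis (ENSG00000109819, chromosome 4, 23755041 to 23904089), did not pass (-0.10 ± 0.11, adjusted p = 0.482), at an RPKM of 0.0526 ± 0.0116 (SD, n = 3) in DMSO and 0.0161 ± 0.0101 in TGFβ, or between 17 and 28 reads against between 4 and 11, a depth and a scale at which a change is hard to see. CDKN1A, the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687337), did not pass (-0.05 ± 0.16, adjusted p = 0.827). POSTN, the matrix protein periostin (ENSG00000133110, chromosome 13, 37562583 to 37598844), was at -0.78 ± 0.41, which did not pass (adjusted p = 0.139), but did with the replicate as a block (adjusted p = 6.24e-04) and without TGFβ replicate 3 (adjusted p = 0.0264, range over all alternatives 1.04e-04 to 0.49). Without replicate 1 or replicate 2 the total of 9131 genes went to 4270 and 3412, and COL1A1 no longer passed (adjusted p = 0.0552 and 0.0693), nor did it with no filter (adjusted p = 0.0586, range over all alternatives 3.83e-04 to 0.0693).

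**Figure D1:**
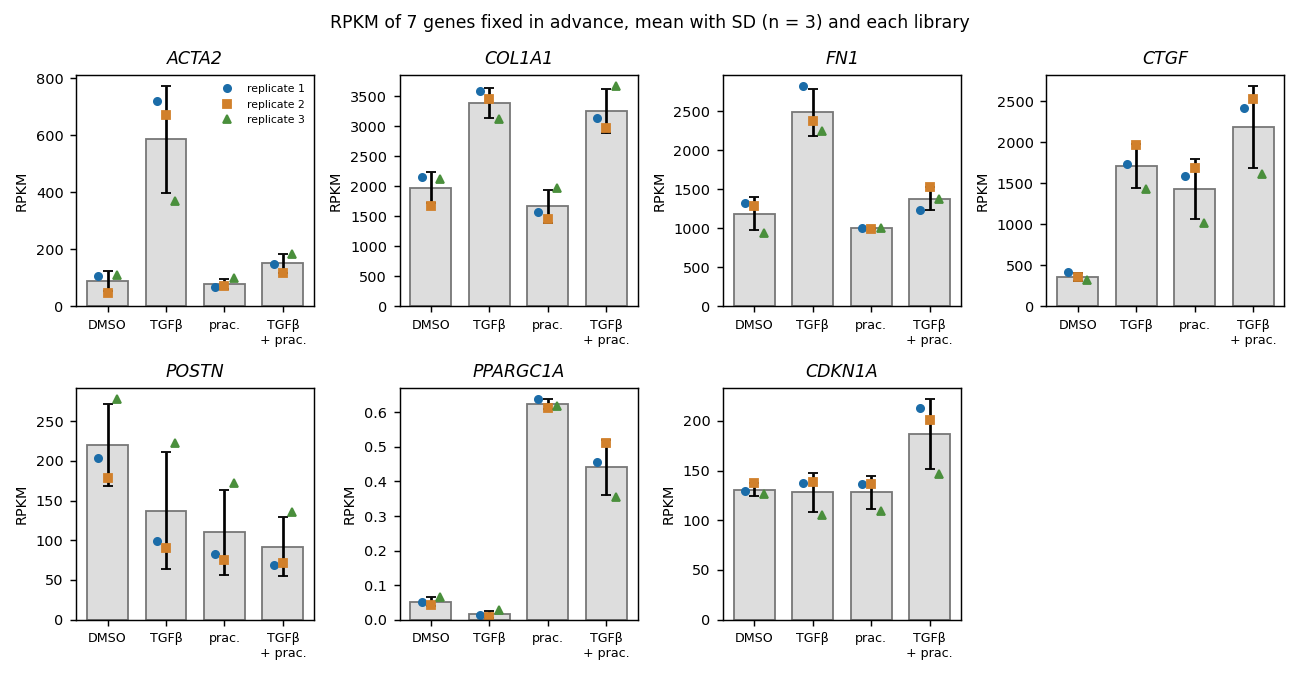
RPKM of 7 genes fixed in advance, with mean and SD (n = 3) as bars and each library as a symbol by replicate. ACTA2 had means of 88.5, 587, 79.3 and 151 and PPARGC1A of 0.0526, 0.0161, 0.624 and 0.441 in DMSO, TGFβ, pracinostat and both.

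Pracinostat alone raised most measured members of a list of genes that are normally restricted to neurons. Of 25 measured neuronal genes 21 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.52, which is 1.46 above that of all genes (adjusted p = 2.60e-08, and adjusted p = 0.245 with an estimated correlation). The Notch ligand DNER rose by 3.45 ± 0.27 (from 0.463 to 9.76 RPKM), the intermediate filament INA by 3.15 ± 0.25, and the synaptic vesicle proteins SYP by 2.85 ± 0.22 and SYN1 by 2.81 ± 0.39. The 5 largest rises in all were the phosphatase PPM1J (3.81 ± 0.15), the muscarinic receptor CHRM4 (3.60 ± 0.09, from 0.0466 to 6.13 RPKM), beta-synuclein SNCB (3.55 ± 0.16), the carboxypeptidase CPA4 (3.55 ± 0.44) and DNER. The 5 largest falls were osteoprotegerin TNFRSF11B (-4.31 ± 0.58, from 122 to 6.17 RPKM), ADH1B (-3.60 ± 0.17), the keratinocyte growth factor FGF7 (-3.54 ± 0.38), the scaffold protein CASS4 (-3.49 ± 0.23) and the activin antagonist follistatin, FST (-3.44 ± 0.27).

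Of 14 genes often raised by HDAC inhibitors 10 rose and 0 fell, also when adjusted over the list alone (10 and 1 with the block). The camera test gave adjusted p = 0.00127 and adjusted p = 0.312 with an estimated correlation. The linker histone H1F0 rose by 2.69 ± 0.16, the metallothioneins MT1X and MT1E by 2.63 ± 0.29 and 1.31 ± 0.27, and the histone HIST2H2BE by 1.03 ± 0.12. Of 12 histone acetyltransferases and acetyl readers 8 fell and 1 rose, also when adjusted over the list alone, including KAT6B (-1.63 ± 0.17), CREBBP (-1.22 ± 0.09), KAT5 (-0.93 ± 0.12) and EP300 (-0.73 ± 0.08). Camera on this list gave adjusted p = 0.00421 and adjusted p = 0.312 with an estimated correlation. HDAC genes went both ways, with 5 that rose and 2 that fell of 10, also when adjusted over the list alone (4 and 3 with median-of-ratios scaling, 5 and 3 with quantile normalization). The list did not pass (adjusted p = 0.783): HDAC3 rose by 1.69 ± 0.13, and HDAC7 and HDAC6 fell by 1.67 ± 0.12 and 0.67 ± 0.09.

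Of 10 genes of serine, glycine and proline synthesis 7 fell and 1 rose (8 and 1 adjusted over the list alone), including MTHFD2 (-2.32 ± 0.17), asparagine synthetase ASNS (-1.50 ± 0.23), MTHFD1L (-1.36 ± 0.12) and PSAT1 (-1.05 ± 0.25). For these genes together the test gave adjusted p = 0.00321 and adjusted p = 0.583 with an estimated correlation. Of 38 cell cycle genes 13 fell and 2 rose (13 and 1 adjusted over the list alone, 14 and 1 with median-of-ratios scaling). The mitotic kinase AURKA fell by 1.17 ± 0.18 and RRM2 by 1.06 ± 0.29, while cyclin CCNE1 rose by 1.17 ± 0.18, and the test gave adjusted p = 0.00855 and adjusted p = 0.919 with an estimated correlation. Of 10 CDK inhibitors and growth arrest genes 2 rose and 1 fell, also when adjusted over the list alone, namely CDKN2D (1.45 ± 0.29), GADD45A (0.71 ± 0.18) and CDKN1B (-0.65 ± 0.17). The list did not pass (adjusted p = 0.747).

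The quiescence, protease, pro-death and pericyte lists did not pass with pracinostat. Of 21 quiescence-linked genes 4 rose and 5 fell (3 and 5 adjusted over the list alone, 7 and 9 with the block), including FGF7, FGF10 (-2.0 ± 0.26) and the nuclear receptor NR4A1 (1.86 ± 0.10), with adjusted p = 0.6. Of 17 proteases 2 rose and 6 fell, also when adjusted over the list alone (3 and 12 with the block), including the membrane-bound collagenase MMP14 (-1.52 ± 0.31), with adjusted p = 0.1 and adjusted p = 0.00513 with the replicate as a block (range over all alternatives 0.00513 to 0.919). Median-of-ratios scaling left 0 proteases that rose and quantile normalization 1, with 6 that fell in either. Of 11 pro-death genes 3 rose and 3 fell, also when adjusted over the list alone, including the death receptor FAS (-2.02 ± 0.21) and BCL2L11, which encodes the death protein BIM (1.98 ± 0.14), with a median of 0.04, a mean of -0.03 and a test that pointed down (adjusted p = 0.727). Of 6 pericyte markers 3 rose and 0 fell, also when adjusted over the list alone (4 and 1 with the block), including MCAM (1.98 ± 0.25) and NOTCH3 (1.76 ± 0.19), with adjusted p = 0.175.

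PPARGC1A rose by 1.02 ± 0.11 (adjusted p = 2.54e-05), from an RPKM of 0.0526 to 0.624 ± 0.0138 (SD, n = 3), or from between 17 and 28 to between 259 and 347 reads, so that the log2 change with the pseudocount understates the ratio of levels. CTGF rose by 1.95 ± 0.23 (adjusted p = 5.75e-05). ACTA2 (-0.08 ± 0.34, adjusted p = 0.86), COL1A1 (-0.25 ± 0.16, adjusted p = 0.224) and CDKN1A (-0.04 ± 0.16, adjusted p = 0.851) did not pass. FN1 (-0.23 ± 0.15, adjusted p = 0.237) passed only without DMSO replicate 3 (adjusted p = 0.034, range over all alternatives 0.034 to 0.649), of the 1-library omissions. POSTN, at -1.07 ± 0.41, was at the threshold (adjusted p = 0.05) and passed with the replicate as a block (adjusted p = 8.14e-05) and without pracinostat replicate 3 (adjusted p = 0.014), and after median-of-ratios scaling (0.0433), with a range over all alternatives of 3.33e-05 to 0.259. In total 5295 genes rose and 3970 fell, of which 1496 and 1034 changed at least 2-fold. After median-of-ratios scaling 4624 rose and 4611 fell, and after quantile normalization 4971 rose and 4569 fell, so the excess of rises depended on the scaling. The total of 9265 went to 5145 without replicate 1 and 5037 without replicate 2.

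Adding pracinostat to TGFβ lowered part of the contractile and matrix genes. ACTA2 fell by 1.92 ± 0.34 (adjusted p = 6.69e-04), from 587 RPKM ± 188 (SD, n = 3) to 151 ± 33. FN1 fell by 0.85 ± 0.15 (adjusted p = 7.26e-04), from 2490 ± 302 to 1380 ± 149. Of 20 contractile genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), among them CNN1 (-1.75 ± 0.27), ACTG2 (-1.59 ± 0.45) and smooth muscle myosin MYH11 (-1.35 ± 0.34), with a median of -0.88, which is -1.07 relative to all genes (adjusted p = 6.15e-06, and adjusted p = 0.521 with an estimated correlation). Of 29 matrix genes 11 fell and 3 rose, also when adjusted over the list alone (17 and 3 with the block), including ELN (-3.60 ± 0.31, from 973 to 75.1 RPKM), CTHRC1 (-2.75 ± 0.41), versican VCAN (-1.74 ± 0.23) and COL8A1 (-1.63 ± 0.23). The list as a whole gave adjusted p = 4.36e-04 and adjusted p = 0.524 with an estimated correlation. Of 23 collagen processing genes 12 fell and 1 rose, also when adjusted over the list alone (14 and 5 with the block, 14 and 0 with median-of-ratios scaling), including the collagen chaperone SERPINH1 (-2.89 ± 0.33), ADAMTS14 (-1.90 ± 0.24) and LOX (-1.63 ± 0.22). The list test gave adjusted p = 0.00101 and adjusted p = 0.298 with an estimated correlation. Some of these falls were also found with pracinostat alone: CTHRC1 (-1.74 ± 0.41), VCAN (-1.11 ± 0.23) and SERPINH1 (-2.10 ± 0.33) fell without TGFβ, and their interactions of -1.01, -0.63 and -0.79 did not pass (adjusted p = 0.323, 0.269 and 0.34). With pracinostat alone 6 matrix genes fell and 3 rose (13 and 4 with the block), 7 collagen processing genes fell and 3 rose (11 and 6 with the block, 10 and 2 with median-of-ratios scaling), and 3 contractile genes fell and 2 rose (4 and 1 with median-of-ratios scaling). None of these 3 lists passed with pracinostat alone (adjusted p = 0.165, 0.305 and 0.689). The matrix list did with the block (adjusted p = 0.0479), but not with the block and an estimated correlation (0.838).

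COL1A1 did not pass on adding pracinostat to TGFβ (-0.06 ± 0.16, adjusted p = 0.776). POSTN (-0.52 ± 0.41) gave adjusted p = 0.311, and 0.00552 with the replicate as a block (range over all alternatives 0.00273 to 0.831). CTGF (0.34 ± 0.23) gave adjusted p = 0.242, and 0.0213 with the block (range over all alternatives 0.0108 to 0.829). The 5 largest falls were LIF (-4.62 ± 0.28, from 75.1 to 2.61 RPKM), the methyltransferase NNMT (-4.39 ± 0.32), PI16 (-3.79 ± 0.36), ELN and the amino acid transporter SLC38A5 (-3.58 ± 0.21). The 5 largest rises were the noncoding RNA NEAT1 (4.23 ± 0.25), the guanylate cyclase subunit GUCY1B3 (4.03 ± 0.14), ANGPTL4 (4.02 ± 1.24), the hormone gene STC1 (3.92 ± 0.66) and GMPR (3.88 ± 0.18). The rise of ANGPTL4 did not pass without TGFβ replicate 1 (adjusted p = 0.0671), TGFβ replicate 2 (0.0645) or replicate 3 of both agents (0.0623), with a range over all alternatives of 3.15e-06 to 0.139. PPARGC1A rose by 0.86 ± 0.11 (adjusted p = 6.34e-05). CDKN1A rose by 0.54 ± 0.16 (adjusted p = 0.014), but did not pass after median-of-ratios scaling (adjusted p = 0.159) or without TGFβ replicate 3 (0.053), or replicate 1 (0.0609) or replicate 2 (0.0535) of both agents, with a range over all alternatives of 1.26e-04 to 0.159.

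Several lists that passed with pracinostat alone also passed with TGFβ present. The cell cycle list did not (6 rose and 4 fell, adjusted p = 0.313, or 3 and 10 with either scaling), but its interaction did not pass either (adjusted p = 0.133), so no difference was shown. Of 25 neuronal genes 21 rose and 0 fell, also when adjusted over the list alone, including DNER (3.18 ± 0.27), INA (3.04 ± 0.25) and STMN2 (3.02 ± 0.25). The test of this list gave adjusted p = 4.10e-06 and adjusted p = 0.298 with an estimated correlation. Of 14 genes often raised by HDAC inhibitors 13 rose and 0 fell, also when adjusted over the list alone (13 and 1 with the block), including H1F0 (3.04 ± 0.16) and GLRX (2.26 ± 0.09). Their list test gave adjusted p = 2.45e-04 and adjusted p = 0.298 with an estimated correlation. Of 12 acetyltransferases and readers 7 fell and 3 rose, also when adjusted over the list alone, including CREBBP (-0.89 ± 0.09) and KAT2B (1.03 ± 0.20). As a list they gave adjusted p = 0.0307, adjusted p = 0.429 with an estimated correlation, and adjusted p = 0.0606 after quantile normalization, which ended the call (range over all alternatives 0.00354 to 0.654). Of 10 serine, glycine and proline genes 9 fell and 1 rose, also when adjusted over the list alone, including MTHFD2 (-3.08 ± 0.17, from 63.2 to 6.95 RPKM) and ASNS (-2.14 ± 0.23). For the list as a whole, the test gave adjusted p = 4.33e-05 and adjusted p = 0.366 with an estimated correlation. Across 19395 genes the pracinostat effects without and with TGFβ correlated at 0.78; 4472 of the 5295 genes that rose without TGFβ also rose with it (84.5%, against 1911 for independent calls), and 2397 of the 3970 that fell also fell (60.4%, against 698).

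Of the genes linked to a resting state, some rose on adding pracinostat. Of 21 quiescence-linked genes 11 rose and 2 fell, also when adjusted over the list alone (9 and 2 with median-of-ratios scaling, 12 and 4 with the block), including the prostaglandin synthase PTGES (2.13 ± 0.20), BMP4 (2.09 ± 0.19) and the prostaglandin receptor PTGER2 (1.91 ± 0.19), while FGF7 fell by 2.27 ± 0.38. The list test did not pass (adjusted p = 0.305). Of 13 BMP signalling genes 7 rose and 3 fell, also when adjusted over the list alone (5 and 3 with either scaling), including the pseudoreceptor BAMBI (1.94 ± 0.28), BMP6 (1.73 ± 0.24) and the inhibitory SMAD6 (1.72 ± 0.17), while FST fell by 2.11 ± 0.27. The list gave adjusted p = 0.844. Of 17 interferon-stimulated genes 6 rose and 2 fell, also when adjusted over the list alone (4 and 3 with either scaling), including IFIT1 (1.92 ± 0.20), while XAF1 fell by 3.28 ± 0.27. That list gave adjusted p = 0.825.

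Many genes moved by TGFβ moved the other way on adding pracinostat. Of 7362 genes that fell with TGFβ, 3847 (52.3%) rose on adding pracinostat, against 2657 expected for independent calls, and of 1769 that rose with TGFβ, 965 (54.6%) fell, against 311 expected. These overlaps were 1717 (50.1%) and 2353 (57.3%) with median-of-ratios scaling and 1723 (48.1%) and 1794 (53.1%) with quantile normalization, so which of them was larger depended on the scaling. Both comparisons use the TGFβ libraries with opposite sign. In simulations of unchanged groups the overlaps were 0 and 0.01 genes on average, the correlation of fold changes across genes was -0.5 against -0.42 in the data, and the covariance was -0.023 against -0.196. These simulations held no changed genes, so hardly any call could overlap. They do not show how many of the real overlaps stem from the shared libraries. The TGFβ group of 3 cannot be divided with at least 2 libraries in each part, so part of the excess may stem from the shared libraries. By the product of the changes, the 10 genes that fell and then rose most were SLC40A1, ADAMTS15, GUCY1B3, CLDN11, GPRC5A, DTX4, NEAT1, CYP2S1, VWA5A and PHLDA1. The iron exporter SLC40A1 changed by -3.10 ± 0.21 with TGFβ and 3.35 ± 0.21 on adding pracinostat, the protease ADAMTS15 by -3.08 ± 0.27 and 3.00 ± 0.27, and GUCY1B3 by -2.26 ± 0.14 and 4.03 ± 0.14. With pracinostat alone NEAT1 was at 2.51, GUCY1B3 at 2.31, VWA5A at 1.59, SLC40A1 at 1.43 and ADAMTS15 at 1.07. Part of their rise was thus also found without TGFβ. CYP2S1 was at 0.22, CLDN11 at -0.54 and DTX4 at -0.98 with pracinostat alone. The 10 that rose and then fell most were LIF, IL11, MEOX1, ELN, PI16, MDFI, SCX, the oxidase NOX4 (3.09 ± 0.11 and -3.22 ± 0.11), KANK4 and the growth factor IGF1 (3.40 ± 0.23 and -2.63 ± 0.23).

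In total 7000 genes rose and 3411 fell on adding pracinostat to TGFβ, of which 2290 and 896 changed at least 2-fold. After median-of-ratios scaling 5054 rose and 5319 fell, after quantile normalization 5175 rose and 5056 fell, and the total of 10411 went to 6087 without replicate 1 and 6202 without replicate 2.

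**Figure D2:**
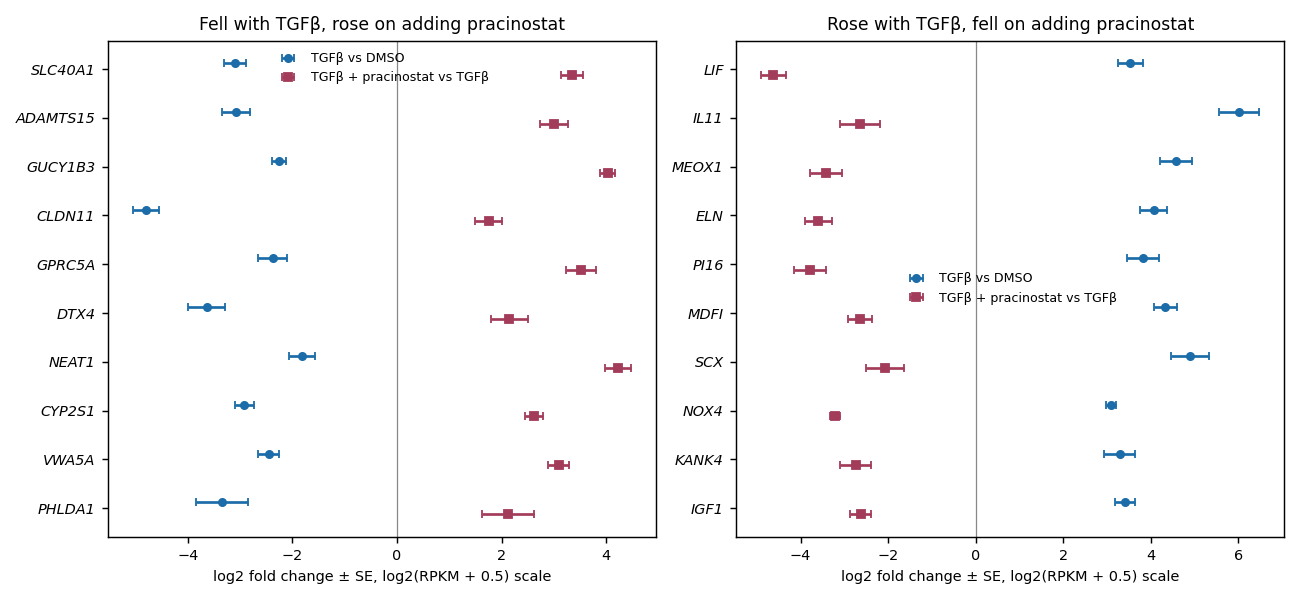
Log2 fold changes with SE of the 10 genes that most fell with TGFβ and rose on adding pracinostat (left, GUCY1B3 at -2.26 and 4.03) and the 10 that most rose and then fell (right, LIF at 3.53 and -4.62).

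In cells given pracinostat, 10 of 14 TGFβ/SMAD targets rose with TGFβ and 0 fell (11 and 0 adjusted over the list alone), with a median of 2.10, which is 2.26 above that of all genes (adjusted p = 1.06e-25), and the call held with an estimated correlation (adjusted p = 0.00384) but not with that and the replicate as a block (adjusted p = 0.0567, the highest over all alternatives). The transcription factor JUNB rose by 3.55 ± 0.17, IL11 by 3.30 ± 0.46 and BHLHE40 by 3.26 ± 0.44. COL1A1 rose by 0.97 ± 0.16 (adjusted p = 0.00453), from 1670 RPKM ± 274 (SD, n = 3) to 3260 ± 370. The COL1A1 call was ended by quantile normalization (0.0602) and by no filter (0.0678), with a range over all alternatives of 0.00109 to 0.218. ACTA2, at 0.92 ± 0.34, did not pass (adjusted p = 0.102), but did with only the 2 groups compared (0.0438, range over all alternatives 0.0438 to 0.459). FN1 was at 0.45 ± 0.15 (adjusted p = 0.0758, 0.0423 after median-of-ratios scaling and 0.0291 with the replicate as a block, range over all alternatives 0.0291 to 0.537). CTGF was at 0.62 ± 0.23 (adjusted p = 0.105, and 0.00484 with the block, range over all alternatives 0.00484 to 0.452). CDKN1A, at 0.54 ± 0.16, gave adjusted p = 0.0524, and 0.00289 with the block, 0.0168 after median-of-ratios scaling, 0.0204 after quantile normalization or 0.0198 without replicate 3 of both agents (range over all alternatives 0.00143 to 0.417). POSTN (-0.23 ± 0.41, adjusted p = 0.746) and PPARGC1A (-0.26 ± 0.11, adjusted p = 0.141) did not pass, the latter except with protein-coding genes only (0.0488, range over all alternatives 0.0488 to 0.539).

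Of 29 matrix genes 8 rose and 0 fell (9 and 0 adjusted over the list alone, 12 and 2 with the block), including COMP (2.87 ± 0.41) and COL5A1 (1.20 ± 0.16). Tested as a list, they gave adjusted p = 4.44e-08 and adjusted p = 0.298 with an estimated correlation. Of 20 contractile genes 2 rose, also when adjusted over the list alone (4 with quantile normalization, 5 with the block), TPM1 (1.38 ± 0.26) and caldesmon CALD1 (0.97 ± 0.13). The camera test gave adjusted p = 1.95e-04 and adjusted p = 0.629 with an estimated correlation. Of 10 CDK inhibitors and growth arrest genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), including GADD45B (2.91 ± 0.28) and the p15 gene CDKN2B (1.89 ± 0.28). Camera on this list gave adjusted p = 1.83e-04 and adjusted p = 0.429 with an estimated correlation. Of 23 collagen processing genes 1 rose and 0 fell, also when adjusted over the list alone (3 and 1 with the block), PLOD2 (1.63 ± 0.17). This list had a median of -0.01, a mean of 0.1 and a test that pointed up (adjusted p = 0.0307, adjusted p = 0.507 with an estimated correlation, and 0.104 after quantile normalization, range over all alternatives 0.0078 to 0.568). Of 13 BMP signalling genes 1 rose and 0 fell, also when adjusted over the list alone (2 and 1 with the block), SMAD6 (0.92 ± 0.17). The BMP list had a median of -0.04, a mean of 0.04 and a test that pointed up (adjusted p = 0.033, adjusted p = 0.312 with an estimated correlation), a call ended by median-of-ratios scaling (0.209), quantile normalization (0.158) and the replicate block (0.0797), with a range over all alternatives of 0.0318 to 0.654. The 5 largest rises were CLDN4 (3.60 ± 0.33), JUNB, endothelin EDN1 (3.38 ± 0.61), IL11 and BHLHE40. The 5 largest falls there were PTX3 (-3.37 ± 0.42), KRTAP1-5 (-3.06 ± 0.18), TCF21 (-2.66 ± 0.28), CLDN11 (-2.52 ± 0.25) and CITED2 (-2.0 ± 0.24).

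In total 559 genes rose and 1741 fell, of which 168 and 61 changed at least 2-fold. Median-of-ratios scaling gave 867 and 350, quantile normalization 855 and 581, and the replicate block 1000 and 4219. The total of 2300 went to 1002 without pracinostat replicate 1, 693 without pracinostat replicate 2, 935 and 880 without replicates 1 and 2 of both agents, 41 without all libraries of replicate 1, 34 without replicate 2 and 6160 without replicate 3. Of the 1769 genes that rose with TGFβ alone, 400 (22.6%) also rose in the presence of pracinostat, against 51 for independent calls, and of the 7362 that fell 1440 (19.6%) also fell, against 661. The first overlap was 714 (17.4%) with median-of-ratios scaling, 666 (19.7%) with quantile normalization and 677 (30.1%) with the block. The second was 268 (7.8%), 418 (11.7%) and 3437 (38.2%), and 918 (13%) with no filter, so its size depended on the processing. These comparisons share no libraries, and their fold changes correlated across genes at 0.61.

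The interaction asked whether the TGFβ effect differed with pracinostat. Of 20 contractile genes 5 passed below 0 and 0 above (10 and 0 adjusted over the list alone, also with the block), including CNN1 (-1.97 ± 0.38) and SMTN (-0.96 ± 0.19). For these genes together the test gave adjusted p = 1.08e-09 and adjusted p = 0.312 with an estimated correlation. For ACTA2 the TGFβ effect was 2.76 without and 0.92 with pracinostat, an interaction of -1.84 ± 0.48 (adjusted p = 0.0355). The ACTA2 call ended without any one of 8 libraries, namely TGFβ replicate 1 (adjusted p = 0.0909) or 2 (0.0882), DMSO replicate 2 (0.0579), pracinostat replicate 1 (0.0604), 2 (0.0629) or 3 (0.0738), and replicate 1 (0.0741) or 2 (0.0842) of both agents. With no filter ACTA2 was at 0.086, and the range over all alternatives was 0.0108 to 0.372. For CTGF the TGFβ effect was 2.23 and 0.62 (-1.61 ± 0.33, adjusted p = 0.0122, but 0.0518 with no filter, range over all alternatives 2.99e-04 to 0.282). CTGF also rose with pracinostat alone (1.95), so its interaction marks rises with either agent that did not add up. FN1 (-0.62 ± 0.21, adjusted p = 0.0974, 0.0319 after quantile normalization and 0.0371 with the replicate as a block, range over all alternatives 0.0319 to 0.499) did not pass. CDKN1A (0.58 ± 0.23, adjusted p = 0.131, 0.00806 with the block and 0.0442 without replicate 3 of both agents, range over all alternatives 0.00442 to 0.568) did not pass, nor did COL1A1 (0.19 ± 0.22, adjusted p = 0.661) and PPARGC1A (-0.16 ± 0.15, adjusted p = 0.572). POSTN (0.55 ± 0.58, adjusted p = 0.61) did not pass either, with a range over all alternatives of 0.00369 to 0.918.

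Of 14 TGFβ/SMAD targets 4 passed below 0 and 2 above (7 and 4 adjusted over the list alone, 6 and 2 with median-of-ratios scaling, 6 and 5 with the block), among the former IL11 (-2.71) and NOX4 (-2.02). That list did not pass (median -0.16, adjusted p = 0.076). Among 29 matrix genes only ELN passed (-2.98 ± 0.43), also when adjusted over the list alone, against 2 below 0 with either scaling, and 7 below and 2 above with the block. The list as a whole gave adjusted p = 2.47e-04 and adjusted p = 0.507 with an estimated correlation. Among 23 collagen processing genes FKBP14 passed (-1.26 ± 0.18), with 6 below 0 and 1 above when adjusted over the list alone, 3 and 0 with median-of-ratios scaling, 2 and 1 with quantile normalization, and 6 and 2 with the block. The list test gave adjusted p = 4.30e-04 and adjusted p = 0.298 with an estimated correlation. Of 21 quiescence-linked genes 6 passed above 0 and 0 below (8 and 0 adjusted over the list alone, 14 and 1 with the block), including BMP4 (2.22 ± 0.27), FGF10 (2.01 ± 0.36), PTGES (1.72 ± 0.29) and the factor KLF4 (1.58 ± 0.29). The test of this list gave adjusted p = 0.00761 and adjusted p = 0.909 with an estimated correlation. Of 17 interferon-stimulated genes 5 passed above 0 and 0 below (6 and 0 adjusted over the list alone, 9 and 0 with the block), including IFIT3 (2.13 ± 0.22), IFIT2 (1.74 ± 0.27) and IFI44 (1.64 ± 0.30). Their list test gave adjusted p = 0.0122 and adjusted p = 0.312 with an estimated correlation. With pracinostat alone 9 of the 17 interferon-stimulated genes fell and 3 rose. IFIT3 and IFIT2 were then at -2.29 and -1.85, and at -0.16 and -0.11 on adding pracinostat to TGFβ. The interactions of IFIT3 and IFIT2 thus mark falls with either agent that did not add up. Of 14 genes often raised by HDAC inhibitors 4 passed above 0 (5 adjusted over the list alone), including GLRX (1.29 ± 0.13), GSN (0.56 ± 0.10) and CLU (0.67 ± 0.14), which did not pass after median-of-ratios scaling (adjusted p = 0.0575, range over all alternatives 0.00178 to 0.331). As a list they gave adjusted p = 0.0361, adjusted p = 0.583 with an estimated correlation, and 0.0846 with the replicate block (range over all alternatives 0.00135 to 0.806). Of 10 HDAC genes 3 passed above 0 (5 adjusted over the list alone, also with the block), but 1 with either scaling. HDAC7 (0.79 ± 0.17) did not pass after median-of-ratios scaling (adjusted p = 0.0834, range over all alternatives 0.00478 to 0.291). For the list as a whole, the test gave adjusted p = 0.0307, adjusted p = 0.312 with an estimated correlation. Median-of-ratios scaling (0.0653) and quantile normalization (0.0761) ended the call of the HDAC list, with a range over all alternatives of 0.00354 to 0.568. Of 10 serine, glycine and proline genes 2 passed below 0, including ALDH18A1 (-1.0 ± 0.19), and SHMT1 (0.72 ± 0.15) passed above (3 and 1 adjusted over the list alone, 4 and 1 with the block). Tested as a list, they gave adjusted p = 0.00815, adjusted p = 0.666 with an estimated correlation, and 0.0713 after quantile normalization (range over all alternatives 0.00503 to 0.666). None of 13 mitochondrially encoded transcripts passed in limma, also when adjusted over the list alone (1 with quantile normalization, 6 with the block), with MT-CO1 at 0.55 ± 0.26 (adjusted p = 0.21, and 0.0263 with the replicate as a block, range over all alternatives 0.0263 to 0.661) and MT-CO2 at 0.39 ± 0.38. The camera test gave adjusted p = 0.00761 and adjusted p = 0.909 with an estimated correlation.

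The 5 largest positive interactions were ADH1B (3.68 ± 0.24), DTX4 (3.12 ± 0.50), the TGFβ signal transducer SMAD3 (2.91 ± 0.33), TOX (2.79 ± 0.34) and C10orf10 (2.77 ± 0.26). The 5 largest negative ones were MEOX1 (-3.94 ± 0.52), PI16 (-3.53 ± 0.51), MDFI (-3.33 ± 0.38), ELN and the zinc-finger gene EGR2 (-2.97 ± 0.25). With pracinostat alone the 5 genes with the largest positive interactions were at -3.60, -0.98, -1.25, -2.43 and -1.37, in the order given. On adding pracinostat to TGFβ they were at 0.08, 2.15, 1.66, 0.36 and 1.40. For ADH1B and TOX the interaction thus mostly marks falls with either agent that did not add up. With TGFβ alone ADH1B already lay well below the 0.5 RPKM added before the log2. This left little room for a further fall, so the interaction of ADH1B is largely set by the scale. In total 1388 genes had positive and 551 negative interactions, of which 484 and 194 were at least 2-fold. Median-of-ratios scaling gave 932 and 1070, quantile normalization 832 and 826, and the replicate block 3133 and 1178. The 7362 genes that fell with TGFβ had a median TGFβ effect of -0.64 without and -0.27 with pracinostat, and the 1769 that rose had medians of 0.67 and 0.19. These genes were chosen by their change without pracinostat, which by itself enlarges the first median of each pair. The interaction also holds the TGFβ and DMSO libraries with the opposite sign, so its direction in such genes is partly set by the choice and is not read as a result. The total of 1939 went to 1128 without TGFβ replicate 1, 1139 without TGFβ replicate 2, 2976 without TGFβ replicate 3, 1170 without DMSO replicate 2, 1214 without pracinostat replicate 2 and 1199 without replicate 1 of both agents. Without all libraries of replicate 1 or of replicate 2 it was 0 in limma, with 2448 and 2114 genes at an unadjusted p under 0.05, and with the block it was then 869 and 625.

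With both agents against DMSO, 10 of 14 TGFβ/SMAD targets rose and 2 fell (11 and 2 adjusted over the list alone), including PMEPA1 (3.61 ± 0.15) and JUNB (3.47 ± 0.17). Camera on this list gave adjusted p = 2.71e-04 and adjusted p = 0.28 with an estimated correlation. Of 25 neuronal genes 20 rose and 0 fell (22 and 0 adjusted over the list alone, 23 and 1 with the block), including INA (3.26 ± 0.25) and SYN1 (3.26 ± 0.39). For these genes together the test gave adjusted p = 1.10e-08 and adjusted p = 0.245 with an estimated correlation. COL1A1 rose by 0.72 ± 0.16 (adjusted p = 0.00267, but 0.103 after quantile normalization and 0.0679 with no filter, range over all alternatives 5.00e-04 to 0.103). CTGF rose by 2.57 ± 0.23 (adjusted p = 7.64e-06) and PPARGC1A by 0.76 ± 0.11 (adjusted p = 1.64e-04). FN1 did not pass (0.22 ± 0.15, adjusted p = 0.244, range over all alternatives 0.0391 to 0.73). ACTA2, at 0.84 ± 0.34, gave adjusted p = 0.0592, and passed with the replicate as a block (0.0465) and without DMSO replicate 1 (0.0467) or DMSO replicate 3 (0.0416), with a range over all alternatives of 0.0334 to 0.23. POSTN fell by 1.30 ± 0.41 (adjusted p = 0.0203), a call that ended without replicate 1 (0.0723) or 2 (0.0709) of both agents or DMSO replicate 3 (0.0665), with a range over all alternatives of 1.69e-05 to 0.162. CDKN1A rose by 0.49 ± 0.16 (adjusted p = 0.023), a call that ended without replicate 1 (0.0924) or 2 (0.0804) of both agents or DMSO replicate 1 (0.0575) or 3 (0.0588), or with no filter (0.0513), with a range over all alternatives of 9.60e-05 to 0.23.

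Of 38 cell cycle genes 20 fell and 1 rose with both agents (23 and 1 adjusted over the list alone), including AURKA (-1.56 ± 0.18), RRM2 (-1.35 ± 0.29), CCNB1 (-1.33 ± 0.26) and TYMS (-1.29 ± 0.19). The list as a whole gave adjusted p = 0.00285 and adjusted p = 0.919 with an estimated correlation. Of 14 genes often raised by HDAC inhibitors 9 rose and 0 fell (9 and 1 adjusted over the list alone, 11 and 1 with the block), including MT1X (2.60 ± 0.29), H1F0 (2.26 ± 0.16) and TUBB3 (1.18 ± 0.15). The list test gave adjusted p = 0.00269 and adjusted p = 0.332 with an estimated correlation. Of 12 acetyltransferases and readers 9 fell and 1 rose, also when adjusted over the list alone (8 and 2 with either scaling, 9 and 2 with the block), including KAT6B (-1.97 ± 0.17) and CREBBP (-1.27 ± 0.09). The test of this list gave adjusted p = 0.00761 and adjusted p = 0.312 with an estimated correlation. Of 10 serine, glycine and proline genes 8 fell, also when adjusted over the list alone, including MTHFD2 (-2.15 ± 0.17) and MTHFD1L (-1.48 ± 0.12). Their list test gave adjusted p = 0.0147 and adjusted p = 0.702 with an estimated correlation. The 5 largest rises were olfactomedin OLFM2 (4.32 ± 0.33), CLDN4 (4.18 ± 0.33), TNFAIP6 (4.11 ± 0.20), PMEPA1 and COMP (3.48 ± 0.41). The 5 largest falls against DMSO were TNFRSF11B (-4.61 ± 0.58), ADH1B (-4.44 ± 0.17), FGF7 (-4.29 ± 0.38), CASS4 (-4.16 ± 0.23) and the hyaluronan-degrading CEMIP (-3.90 ± 0.46). In total 4369 genes rose and 5689 fell, of which 1316 and 1496 changed at least 2-fold. After median-of-ratios scaling 5148 rose and 4827 fell, and after quantile normalization 5097 rose and 5042 fell, so which direction held more genes depended on the scaling. The total of 10058 went to 5817 without replicate 1 and 5442 without replicate 2.

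**Figure D3:**
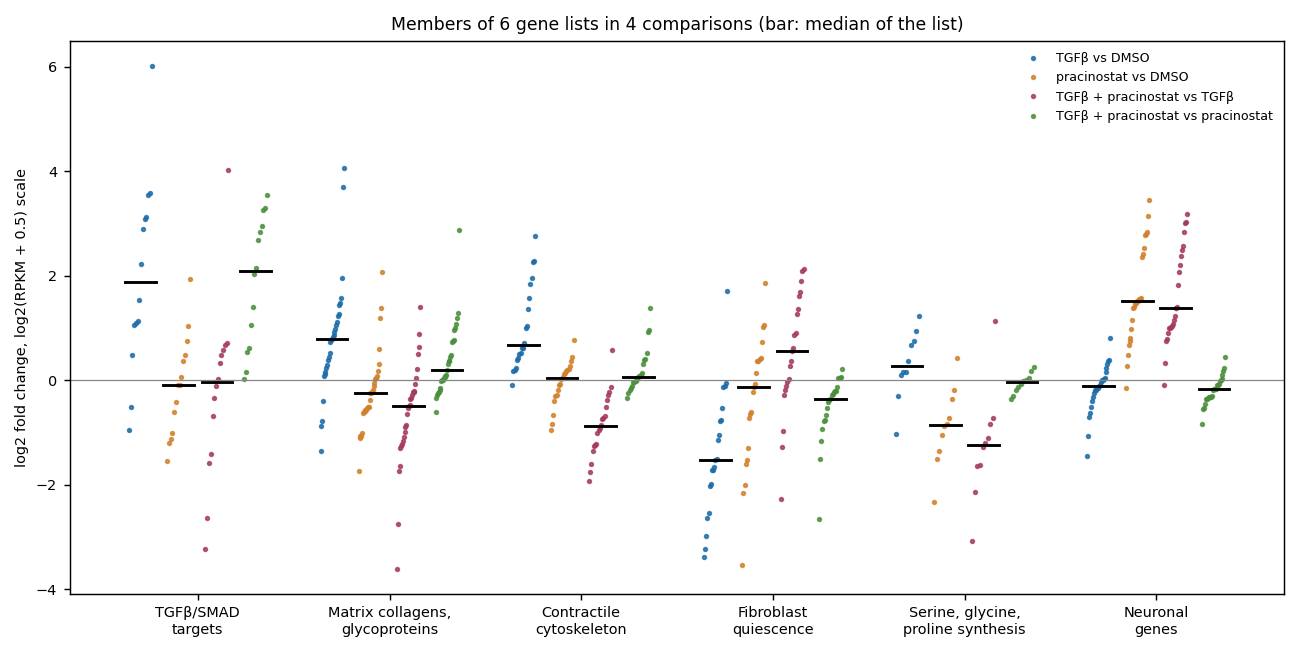
Log2 fold changes of the members of 6 lists in 4 comparisons, with bars at list medians. The median of the TGFβ/SMAD targets was 1.89 with TGFβ alone and 2.10 with TGFβ in the presence of pracinostat, and that of the neuronal genes was 1.52 with pracinostat alone; quantile normalization ended the TGFβ call of the serine, glycine and proline list (adjusted p = 0.0727).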

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

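The 2 tests of smaller TGFβ responses under pracinostat (held-out replicates, scaling), that of raised against lowered genes and the regroupings within replicates were chosen only after the result was seen. Of 167 named genes, 61 had a TGFβ effect that differed with and without pracinostat by the interaction test, 40 with a positive and 21 with a negative interaction, each in 3 of 3 replicates, which the naming rule required of the largest. Among all 19395 genes 1939 did, 1388 with a positive and 551 with a negative interaction. The rule took in the largest interactions and the largest TGFβ changes, so the share and signs among named genes are partly set by the choice. They are given here as log2 interactions, grouped by function for reading only, and no such group was tested here.

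Positive interactions among enzymes and transporters were ADH1B 3.68, RDH10 2.75, SLC7A14 2.5, CYP2S1 2.40, SLC40A1 1.92, PTGES 1.72, GUCY1B3 1.72, GMPR 1.55, GLRX 1.29, TYMS 0.98, SAT1 0.76 and SHMT1 0.72. Signalling and transcription genes were DTX4 3.12, SMAD3 2.91, TOX 2.79, BMP4 2.22, FGF10 2.01, KLF4 1.58, SMAD6 1.54, PTGER2 1.48, CCL2 1.39 and CEBPD 1.12. Interferon-stimulated genes were IFIT3 2.13, IFIT2 1.74, IFI44 1.64, IFIT5 0.71 and IFI6 0.60, and chromatin enzymes were HDAC5 1.27, KAT2B 1.14, HDAC7 0.79 and HDAC11 0.51. Others were C10orf10 2.77, CLDN11 2.29, ADAMTS15 1.93, NEAT1 1.72, CASS4 1.66, VWA5A 1.49, PLAT 1.42, CLU 0.67 and GSN 0.56. With pracinostat alone the genes with positive interactions went both ways, from -3.60 for ADH1B to 2.51 for NEAT1. A positive interaction alone therefore does not show that pracinostat reversed a TGFβ effect.

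Negative interactions among enzymes and transporters were SLC38A5 -2.44, NOX4 -2.02, ALDH18A1 -1.0 and PSPH -0.74. Contractile genes were CNN1 -1.97, ACTA2 -1.84, MYH11 -1.73, SMTN -0.96 and CALD1 -0.87, and matrix and matrix-handling genes were ELN -2.98, CTGF -1.61, FKBP14 -1.26 and ADAMTS4 -0.91. Cytokines and growth factors were IL11 -2.71, LIF -2.35 and IGF1 -2.25. Transcription regulators were MEOX1 -3.94, MDFI -3.33 and EGR2 -2.97. Others were PI16 -3.53 and KANK4 -2.74. With pracinostat alone the genes with negative interactions also went both ways, from -2.27 for LIF to 1.95 for CTGF. CTGF and FKBP14 were at 2.23 and 1.23 with TGFβ alone and at 1.95 and 1.09 with pracinostat alone. On adding pracinostat to TGFβ they were at 0.34 and -0.17. A negative interaction alone therefore does not show that pracinostat lowered a gene raised by TGFβ.

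The alternatives were run for 34 of these genes, and all 34 lost their call without replicate 1 and all 34 without replicate 2, against 0 without replicate 3 and 0 with the replicate as a block. Of the 34, 7 lost it without a single library: ACTA2, given with the results, and 6 others. MYH11 (adjusted p = 0.0448) did so without 9 of the 12 libraries, at 0.06 without pracinostat replicate 1 to 0.107 without TGFβ replicate 1 and at 0.104 with no filter (range over all alternatives 0.00255 to 0.432). HDAC5 (0.0363) did so without the same 9, at 0.0547 without TGFβ replicate 1 to 0.0894 without replicate 1 of both agents and also with no filter (0.0836) and after quantile normalization (0.0666, range 4.95e-04 to 0.354). PSPH (0.0408) did so without 10, at 0.0529 without pracinostat replicate 3 to 0.104 without TGFβ replicate 1 and also with no filter (0.0827, range 0.00424 to 0.548). IFIT5 (0.0213) did so without 6, at 0.0536 without pracinostat replicate 2 to 0.0584 without TGFβ replicate 2 (range 0.0011 to 0.47). SAT1 (0.021) did so without DMSO replicate 2 (0.054) or TGFβ replicate 2 (0.0562, range 0.00296 to 0.39), and HDAC11 (0.0184) without TGFβ replicate 2 (0.0548) or pracinostat replicate 2 (0.0531), after median-of-ratios scaling (0.056) and after quantile normalization (0.146, range 0.0108 to 0.48).

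The median TGFβ response of genes that passed with TGFβ was smaller under pracinostat. The TGFβ/SMAD targets had list medians of 1.89 without and 2.10 with it, or 2.16 and 2.26 relative to all genes. Their median interaction was -0.16, and the interaction test of that list did not pass (adjusted p = 0.076). After median-of-ratios scaling the list medians were 2.25 and 2.27 and the median interaction was -0.37, with 2 members that passed above 0 and 6 below. For genes chosen in 2 replicates and measured in the remaining one, the median change with pracinostat was 0.38, 0.36 and 0.47 of that without. This argues against choice of genes by their response in the same libraries as the whole cause. The genes were still chosen by their response without pracinostat, and the opposite choice was not run. A weaker response to TGFβ in general is therefore not shown. After median-of-ratios scaling the ratios for genes that fell were at most 0.29, which argues against scaling to mapped reads. Whether genes lowered by TGFβ kept less of their response than genes raised by it cannot be told apart from no difference, since the mean gap was -0.09 with a range of -0.31 to 0.03, against 0.05 to 0.12 after median-of-ratios scaling. Of 1336 genes that fell with TGFβ and had a positive interaction, 596 also fell with pracinostat alone, 307 rose and 433 did not pass. Of 507 that rose with a negative interaction, 179 also rose with pracinostat alone, 108 fell and 220 did not pass. A move of the same genes by pracinostat alone may thus account for part. These calls share the DMSO libraries, so the counts cannot settle it. The cause stays open, and an effect of HDAC inhibition on TGFβ signalling was not tested.

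More genes fell than rose with TGFβ in values scaled to mapped reads. After median-of-ratios scaling more rose than fell, and after quantile normalization the numbers were close. The 50 genes that gained most in read share, among them FN1, COL1A1, TGFBI and ELN, went from 12% ± 0.928 (SD, n = 3) of reads in DMSO to 24% ± 1.99 in TGFβ, and by themselves would lower all other genes by a log2 of -0.21 ± 0.04 (SD), against a median shift of -0.27 ± 0.07. A larger share taken by a few abundant genes is therefore of a size that could account for most of the shift. The 50 genes were chosen for this gain in the same libraries, and a fall of many other genes would raise their share too. The value cannot tell these apart. No spike-in was available, so a change in total RNA per cell stays open.

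Of 25 neuronal genes 21 rose with pracinostat. The list median of 1.52 was at percentile 100 of 10000 random lists matched on the DMSO level, whose highest median was 0.92, which argues against the filter on low values as the cause. Release of neuronal genes from repression by HDACs may underlie it and was not tested.

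The 6 libraries of each comparison of 2 groups can be divided in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10, the real one, gave as many genes. The real counts and the highest of the others were 9131 and 1 for TGFβ, 9265 and 1 for pracinostat, 10411 and 0 for adding pracinostat to TGFβ, 2300 and 1 for adding TGFβ to pracinostat, and 10058 and 0 for both against DMSO. For the interaction 2 of 100 regroupings gave at least the real 1939 genes, the real one included. The other gave 2562, with all 3 TGFβ libraries and all 4 libraries of replicate 3 on one side. A TGFβ effect and a structure of the samples by replicate may both have stayed in it and were not told apart. With the replicate as a block the interaction count was 4311. Of 100 regroupings within replicates, the real one included, 5 gave at least as many genes, both without the block (highest other 8991) and with it (9271), so the share was not under 0.05 and chance is not excluded. The other 4 set at least 10 of the 12 libraries apart by one of the treatments, so the effect of that treatment stayed in their counts. The 75 that set at most 8 apart gave at most 211 genes, or 363 with the block.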

How the results depend on the processing

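Restricting to protein-coding genes, the replicate block without 1 replicate, and the block with an estimated correlation were chosen after seeing the data. Of 311 named gene results 285 passed, 0 of these changed sign in any alternative, and 95 lost their call in at least 1, of which 28 in alternatives that keep every library. Of 43 list calls, 42 held with log2(RPKM + 0.1), 43 with log2(RPKM + 1), 41 with no filter, 40 with the stricter filter, 40 with median-of-ratios scaling, 36 with quantile normalization, 40 with the replicate block, 2 with an estimated correlation and 0 with both of these.

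At least 2-fold changes numbered 1998 with TGFβ, 2530 with pracinostat, 3186 on adding pracinostat to TGFβ, 229 on adding TGFβ to pracinostat, 2812 with both and 678 in the interaction, since the limit removes smaller changes. Without 1 replicate the counts ranged from 3412 to 12033, 5037 to 11785, 6087 to 12684, 34 to 6160, 5442 to 12443 and 0 to 5528 (limma; 2448, 2114 and 7961 interactions at an unadjusted p under 0.05 without replicate 1, 2 and 3). Groups then hold 2 libraries, yet interactions were 0 without replicate 1 or 2 and 5528 without 3, which argues against group size alone. The cause was not tested. For adding TGFβ to pracinostat the count was 1217 with median-of-ratios scaling, 1436 with quantile normalization, and with the block 5219, or 456, 316 and 5984 without replicate 1, 2 and 3. For the interaction the counts with the block were 4311, 869, 625 and 5434 in the same order. With the block, matrix genes with pracinostat (adjusted p = 0.0479), quiescence-linked genes on adding TGFβ to pracinostat (0.0106) and CDK inhibitors with both agents (0.0366) also passed as lists. With an estimated correlation as well, these lists did not pass (0.838, 0.374 and 0.654). Beyond the values given above, the block changed no other call of the named genes and lists recomputed. It moved none of the other totals and overlaps of genes given here by more than 1.5 times. Counts of list members that it moved further are given with each list.

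The overlap of genes that fell with TGFβ and rose on adding pracinostat was 1717 with median-of-ratios scaling and 1723 with quantile normalization, and that of genes that rose and then fell 2353 and 1794. Genes that rose with TGFβ without and with pracinostat numbered 714, 666 and, with the block, 677, and those that fell both times 268, 418 and 3437, and 918 with no filter. The cause was not tested.

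Results that did not pass changed sign as follows, and the cause was not tested. With TGFβ, the protease list, whose test pointed up, had medians of -0.23 with no filter, -0.14 with median-of-ratios scaling, -0.3 with quantile normalization and -0.5 with the block, also with an estimated correlation, and tests that pointed down. The inflammatory list did so at -0.18, -0.36 and -0.29 with no filter and the 2 scalings. The pro-death list turned up with no filter (pracinostat, median 0.11) and the interferon list turned down with the stricter filter (adding pracinostat to TGFβ, median 0.11). CDKN1A with TGFβ was at 0.33 with median-of-ratios scaling, 0.08 without TGFβ replicate 3 and 0.05 without replicate 3, also with the block (range without libraries -0.12 to 0.08). ACTA2 with pracinostat was at 0.11 without DMSO replicate 1 or 3 and 0.19 without replicate 1, also with the block (range -0.47 to 0.19), and CDKN1A at 0.07 without pracinostat replicate 3 and 0.04 without replicate 3, also with the block (range -0.11 to 0.07). COL1A1 on adding pracinostat to TGFβ was at 0.01 without replicate 2 of both agents or without replicate 1 and 0.02 without replicate 2, also with the block (range -0.21 to 0.02). POSTN on adding TGFβ to pracinostat was at 0.14 without pracinostat replicate 3 (range -0.54 to 0.14), and COL1A1 in the interaction at -0.06 with quantile normalization. Depth limits genes such as PPARGC1A, with between 4 and 11 reads in TGFβ.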

Other observations

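Cholesterol synthesis genes (18 measured) and heterochromatin and H3K9 methylation genes (9 measured) did not pass as lists in any of the 12 tests (camera, limma), and 0 of the 12 had an unadjusted p under 0.05. The single genes here were chosen after their values were seen. CYP51A1, a sterol demethylase, fell with both agents by 1.51 ± 0.32 (SE, adjusted p = 0.00235) and on adding pracinostat to TGFβ by 1.21 ± 0.32 (adjusted p = 0.00784). EHMT2, an H3K9 methyltransferase, fell with TGFβ by 1.08 ± 0.13 (adjusted p = 9.00e-05) and rose on adding pracinostat by 0.97 ± 0.13 (adjusted p = 9.84e-05). SETDB1, another, fell with pracinostat by 0.71 ± 0.10 (adjusted p = 1.30e-04). The inhibitory SMAD7 had a positive interaction of 1.13 ± 0.22 (adjusted p = 0.00909), and the cytokine IL6 fell on adding pracinostat to TGFβ by 1.87 ± 0.18 (adjusted p = 9.50e-06). Each of these changes had the same direction in 3 of 3 replicates, and the alternatives were not run for these genes.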
